A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

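The data come from SRM11, a long-lived Saccharomyces cerevisiae mutant derived, per the labels, from a haploid laboratory strain of mating type a. The labels' protocols describe 16 h precultures and 3 SRM11 cultures grown from an OD600 of 0.1 at 30 °C and 150 rpm in a minimal medium that held 0.67% nitrogen base and, as sugar, 2% glucose. Cells were harvested at an OD600 of 1.0, total RNA was extracted with a column kit, and 200 ng was labelled with the dye Cy3 and hybridised to an Agilent one-color yeast array. Each array gave 13048 spots, of which 12512 were the 6256 gene probes, each spotted 2 times.

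Spot intensity was deposited by the authors for each array, on a linear scale, as processed, background-subtracted and median pixel signals with quality flags. Feature Extraction 10.7.3.1 made these intensity values per the file headers, while the submitters' processing notes name Agilent Feature Extraction 9.1. The deposited table of the whole series holds log2 values for 6316 probes, 60 of them control probes, each relative to a baseline of its own probe. How that table was made is not given in the sources used here. It also holds 3 columns whose names match none of the samples described here, and these were not used. Whether these columns are among the arrays behind the baseline, or hold the reference strain, is not stated in the sources used here.

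What the log2 values are relative to was examined on the 3 SRM11 columns alone. The 3 columns had the same mean of -0.000298, as quantile normalization gives. In 5.94% of probes, a pair of SRM11 values summed to 0 within 1e-05, against 0.00554% on average over 20 shufflings of the columns. Such pairs arise where the baseline is a median over an even number of arrays that includes the SRM11 arrays. Differences between arrays in the table followed the differences in log2 processed intensity across detected genes. The intensities had been quantile-normalized here for this comparison. Pearson's r ran from 0.97 to 0.98 and slopes from 0.96 to 0.99. These are correlations across genes, which are not independent replicates. The unit is therefore log2, and 0 is the baseline, not the reference strain. Which further arrays stand in the baseline is not stated in the sources used here, so a difference in batch or handling between them and the SRM11 arrays cannot be told apart from the strain. The headers place the 3 SRM11 arrays on 1 slide.

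The mean of the 3 SRM11 values was tested against 0 for each of the 6256 gene probes with limma 3.58.1 in R 4.3.3 (moderated test, two-sided, 2 residual degrees of freedom, prior of 2.37 degrees of freedom), with Benjamini-Hochberg adjustment. A gene is said to have risen or fallen where its adjusted p was under 0.05, and counts also use a distance of 2-fold from the baseline. All gene probes were tested, because a filter on SRM11 signal removes genes that fell. The plan of alternatives had worded the filter as the default and no filter as its alternative, for this test and for levels, and this was settled after the files had been seen. The test was checked on data simulated with a median baseline over as many other arrays. A simulated log2 difference of 1 between strains gave a median value of 0.50, and a difference of 2 gave 1.01, so the values understate differences between strains if the baseline is such a median. Of 50 genes simulated at a log2 difference of 1, 39 passed the adjusted p and 1 passed the 2-fold threshold too. At a difference of 2 these numbers were 48 and 30. None of 6056 simulated unchanged genes passed, at 6256 genes in the step. The simulation held no offset between the 3 arrays and the others, so this count does not cover a difference in batch or handling.

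Gene lists, 36 in number, were written before the data were examined. One entry of 885 matched no gene on the array. Each list was tested with camera at its preset correlation of 0.01 and at an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance. With 3 arrays, the estimated correlation and the test that uses it rest on 2 residual degrees of freedom. A list not called that way is therefore not shown to be unchanged. The median of each list was also placed among 10000 random lists matched on mean signal in 10 bins. Gene names came from the RefSeq table of assembly GCF_000146045.2, in which 5756 gene probes had a locus and 500 had none. The build of the array differs or is not named, so that table was used for names and neighbours and no coordinates are given.

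For expression levels, log2 processed signals, with signals under 1 set to 1, were summarised by the median of the spots and scaled to a common 75th percentile, using Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. A gene counted as detected where most of its spots were flagged well above background in all 3 arrays. The spread between cultures is the SD over the 3 arrays, and the spread between spots is the SD between the spots of one array. Each culture has 1 array, so the spread between cultures includes that of RNA preparation, labelling and hybridisation. The number of arrays, 3, limits the precision of every value. The labels say that the cultures were inoculated in triplicate from the precultures, and do not say whether each had its own preculture.

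Named genes followed a rule fixed before the data were examined. They are the 12 largest rises past the threshold among genes detected in all 3 arrays and the 12 largest falls, leaving out probes absent from the RefSeq table. For each list described, up to 4 members with the largest absolute change were added. For levels they are the 12 highest signals with the 2 highest and 2 lowest members of a list, and for spread the 10 largest SDs among detected genes. Alternatives covered the fold and p thresholds, the filter, centring, leaving out each array, the signal column, the scaling and the detection rule.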

Results

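Expression was measured on 3 one-color arrays, each of RNA from a separate log-phase culture of SRM11, a yeast mutant with a long chronological lifespan. All 3 samples form a single group. The median processed signal of the gene spots was 1288, 1187 and 1270 in replicates 1, 2 and 3, which was 281, 304 and 250 times the median of the negative control spots. Between 92.4% and 93.5% of gene spots lay well above background, and no gene spot was saturated. The series sets out to compare SRM11 with the reference strain in log phase. That comparison is given here as log2 values relative to a baseline of each probe, which is not the reference strain itself, so each value is a distance from the baseline and not a fold change between strains. If the baseline is a median over the SRM11 arrays and as many arrays of another strain, a log2 difference of 1 between strains gives a value of about 0.50, as simulated.

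The 12 genes farthest above the baseline in SRM11 were led by HXK1, YMR206W, GPH1 and HSP26, and the 12 farthest below it by PHO84, BI2, ARO3 and ERG20. HXK1 (YFR053C), which encodes a hexokinase, was highest at 3.53 ± 0.06 (SD, n = 3) on the log2 scale, an 11.6-fold distance. It was followed by YMR206W, at 3.50 ± 0.31, and by GPH1 (YPR160W), the glycogen phosphorylase gene, at 3.28 ± 0.19. HSP26 (YBR072W), a small heat shock protein gene, lay at 3.27 ± 0.13, and TMA10 (YLR327C) at 2.99 ± 0.13. HXT7 (YDR342C) and HXT6 (YDR343C), genes of near-identical hexose transporters whose probes may not tell them apart, lay at 2.93 ± 0.28 and 2.88 ± 0.25. The remaining highest genes were ISF1 at 2.90 ± 0.38, CYC7 (YEL039C), which encodes an isoform of cytochrome c, at 2.80 ± 0.28, GPM2 at 2.64 ± 0.04, RGI1 at 2.63 ± 0.23 and YNL194C at 2.62 ± 0.06.

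The lowest value was that of PHO84 (YML123C), the high-affinity phosphate transporter gene, at -3.57 ± 0.38 (SD, n = 3). ARO3 (YDR035W), an enzyme gene of aromatic amino acid synthesis, lay at -2.97 ± 0.81, and ERG20 (YJL167W), the farnesyl pyrophosphate synthase gene, at -2.71 ± 0.21. Ribosome assembly genes among the lowest were SDA1 (YGR245C) at -2.69 ± 0.12, NSR1 (YGR159C) at -2.54 ± 0.06 and RSA4 (YCR072C) at -2.40 ± 0.10, with the RNA helicase gene DBP2 (YNL112W) at -2.53 ± 0.05. ZRT1 (YGL255W), the high-affinity zinc transporter gene, lay at -2.47 ± 0.02, the adenine deaminase gene AAH1 (YNL141W) at -2.39 ± 0.18 and PCS60 (YBR222C) at -2.67 ± 0.51. The mitochondrial intron genes BI2 and AI1 lay at -2.97 ± 0.30 and -2.37 ± 0.21. BI2 and ARO3 were not above background in any SRM11 array, and PHO84 and PCS60 were above it in 1 array each, so background sets the size and rank of these 4 values. Adjusted p values of these 24 genes ran from 7.62e-05 to 0.00142 in limma, and each gene lay on the same side of the baseline in 3 of 3 arrays.

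**Figure D1:**
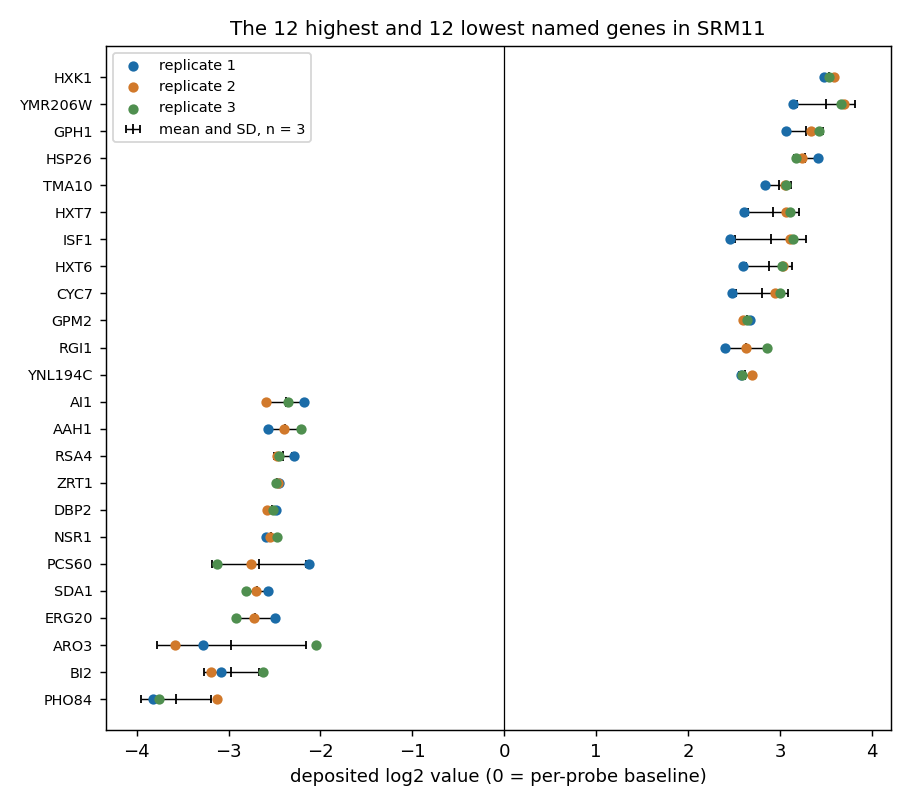
Deposited log2 values (horizontal axis, 0 is the baseline of each probe) of the 12 highest and 12 lowest named genes, with 1 coloured point per SRM11 array and a black bar for the mean and SD of 3 arrays. HXK1 is at the top with 3.53 and PHO84 at the bottom with -3.57, and the widest bar is that of ARO3, with an SD of 0.81.

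Over the whole array, 270 of 6256 genes lay at least 2-fold above the baseline and 347 at least 2-fold below it at an adjusted p under 0.05 in limma. Without the fold threshold 2346 genes rose and 2174 fell. All 3 arrays lay on one side of the baseline in 82.3% of genes, against 10.2% of simulated unchanged genes. The simulation held no offset in batch or handling, so the 82.3% cannot be read as a share of strain differences. The median of all genes was 0.02.

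Genes of the general stress response rose together. Of 34 members 31 rose and 1 fell, with a list median of 1.20, and the counts adjusted over the list alone were also 31 and 1. TMA10 rose by 2.99 ± 0.13 (SD, n = 3), DDR2 by 2.56 ± 0.29, HSP12 by 2.42 ± 0.05 and SOL4 by 2.08 ± 0.06. The list was called with camera at its preset correlation (adjusted p = 1.18e-09) and not called at an estimated correlation (adjusted p = 0.456). Of 33 heat shock protein and chaperone genes 28 rose and 3 fell, both over all genes and adjusted over the list alone, with a median of 0.91. Next to HSP26 and HSP12, SSA4, an Hsp70 gene, rose by 2.03 ± 0.29 and BTN2 by 1.91 ± 0.32. The camera adjusted p was 1.29e-05, and with an estimated correlation the adjusted p was 0.585.

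Of 20 genes of trehalose and glycogen metabolism 18 rose and none fell, with a median of 0.97; adjusted over the list alone, 18 rose and 1 fell. GPH1 led the list, followed by TSL1, a subunit gene of trehalose synthase, at 2.48 ± 0.15 (SD, n = 3), the phosphoglucomutase gene PGM2 at 2.29 ± 0.07 and the glycogen synthase gene GSY1 at 2.11 ± 0.18. The camera adjusted p was 1.03e-05, and with an estimated correlation the adjusted p was 0.338. Oxidative stress defence genes rose in 23 of 38 cases and fell in 3, with a median of 0.47 and the same counts adjusted over the list alone. The glutaredoxin gene GRX1 rose by 1.64 ± 0.18, the sulfiredoxin gene SRX1 by 1.44 ± 0.12 and the catalase gene CTT1 by 1.40 ± 0.16. Of 35 autophagy genes 27 rose and 2 fell, again with the same counts adjusted over the list alone and a median of 0.45, led by ATG39 at 1.47 ± 0.25 and ATG8 at 1.40 ± 0.07. Both lists had a camera adjusted p of 0.00015, and both had an adjusted p of 0.338 with an estimated correlation.

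Of 20 genes of gluconeogenesis, the glyoxylate cycle and non-fermentable carbon use 17 rose and none fell (18 rose when adjusted over the list alone), with a median of 0.83. The lactate transporter gene JEN1 rose by 2.04 ± 0.45 (SD, n = 3), SFC1 by 1.59 ± 0.84, CRC1 by 1.31 ± 0.25 and the regulator gene CAT8 by 1.19 ± 0.24. Of 14 genes of galactose and maltose use 11 rose and none fell, with the same counts adjusted over the list alone and a median of 0.61. The maltase genes MAL12 and MAL32, which are near-identical and may share signal, rose by 2.47 ± 0.27 and 2.22 ± 0.27, the transporter gene MAL11 by 2.18 ± 0.25 and GAL7 by 1.33 ± 0.08. Camera adjusted p values were 0.000443 and 0.00417, and with an estimated correlation both lists had an adjusted p of 0.585. Of 22 genes of hexose transport and sensing 13 rose and 3 fell, with the same counts adjusted over the list alone. Beside HXT7 and HXT6, HXT2 rose by 1.99 ± 0.51 and MTH1 by 1.66 ± 0.27. The median was 0.36, with a camera adjusted p of 0.0491 and an adjusted p of 0.497 with an estimated correlation; the call was lost among detected genes and without replicate 2.

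Respiratory chain and ATP synthase genes rose in 26 of 43 cases and fell in 4, with a median of 0.33. CYC7 led, followed by STF1 at 1.86 ± 0.09 (SD, n = 3), COX5B at 1.53 ± 0.10 and COX7 at 0.97 ± 0.19. Of 18 genes of the tricarboxylic acid cycle 11 rose and 3 fell, with a median of 0.30, among them SDH1 at 0.91 ± 0.07 and CIT1 at 0.87 ± 0.03. Of 17 glycolysis genes 13 rose and none fell, with a median of 0.27. Among the 13, FBA1 at 0.10 and GPM1 at 0.19 had the same value in all 3 arrays, although their signals differed. Their SD of 0 is thus no measure of spread. The members that moved most were HXK1, the glucokinase gene GLK1 at 1.38 ± 0.02, TDH1 at 1.00 ± 0.23 and PYK2 at 0.99 ± 0.04. The counts of these 3 lists were the same adjusted over the list alone. Camera adjusted p values were 0.00329, 0.0403 and 0.00132, and with an estimated correlation the adjusted p was 0.585, 0.456 and 0.456. The call of the tricarboxylic acid cycle was lost without replicate 1. Among random lists matched on signal, the respiratory chain median lay at percentile 99.8, that of the tricarboxylic acid cycle at 95.2 and that of glycolysis at 90.0. Seripauperins, a family of near-identical subtelomeric genes, rose in 22 of 24 cases and fell in 1, with the same counts adjusted over the list alone. Their median was 0.44 with a camera adjusted p of 6.74e-05, and the adjusted p was 0.497 with an estimated correlation.

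Ribosome biogenesis genes had the lowest median of the 36 lists. Of 54 members 53 fell and none rose, 44 of them at least 2-fold, with a median of -1.26 and the same counts adjusted over the list alone. The examples with the largest fall were NSR1 and DBP2, followed by DBP9 at -2.04 ± 0.08 (SD, n = 3) and DRS1 at -1.78 ± 0.12, both RNA helicase genes. The camera adjusted p was 9.46e-18, and with an estimated correlation the adjusted p was 0.338. Of 138 ribosomal protein genes 110 fell and 2 rose, but by less, with a median of -0.36, and 3 of them fell at least 2-fold. RPL41B lay at -1.16 ± 0.10, RPL21A at -1.16 ± 0.08 and RPS28B at -1.02 ± 0.21. Of 22 translation factor genes 19 fell and none rose, with a median of -0.38, led by SUI1 at -1.32 ± 0.15 and the elongation factor gene YEF3 at -1.17 ± 0.07. Both lists kept their counts adjusted over the list alone. Camera adjusted p values were 4.25e-13 and 7.5e-05, and with an estimated correlation the adjusted p was 0.497 and 0.338.

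Amino acid biosynthesis genes fell in 37 of 55 cases and rose in 7, with a median of -0.27 and the same counts adjusted over the list alone. After ARO3 came the activator gene GCN4 at -0.99 ± 0.14 (SD, n = 3), ARO7 at -0.89 ± 0.04 and HIS3 at -0.81 ± 0.05. The camera adjusted p was 0.000237, and with an estimated correlation the adjusted p was 0.585. Of 23 genes of zinc and phosphate uptake 15 fell and 3 rose, with the same counts adjusted over the list alone and a median of -0.26. PHO84 and ZRT1 fell most, followed by ADH4, a zinc-regulated alcohol dehydrogenase gene, at -2.19 ± 0.10 and PHM6 at -1.89 ± 0.22. The camera adjusted p was 0.00404, and with an estimated correlation the adjusted p was 0.456. Of 8 genes used as auxotrophic markers in laboratory strains 6 fell and 1 rose (7 fell and 1 rose adjusted over the list alone), with a median of -0.35, a camera adjusted p of 0.0318 and an adjusted p of 0.456 with an estimated correlation. HIS3 and LYS2, at -0.58 ± 0.10, moved most.

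**Figure D2:**
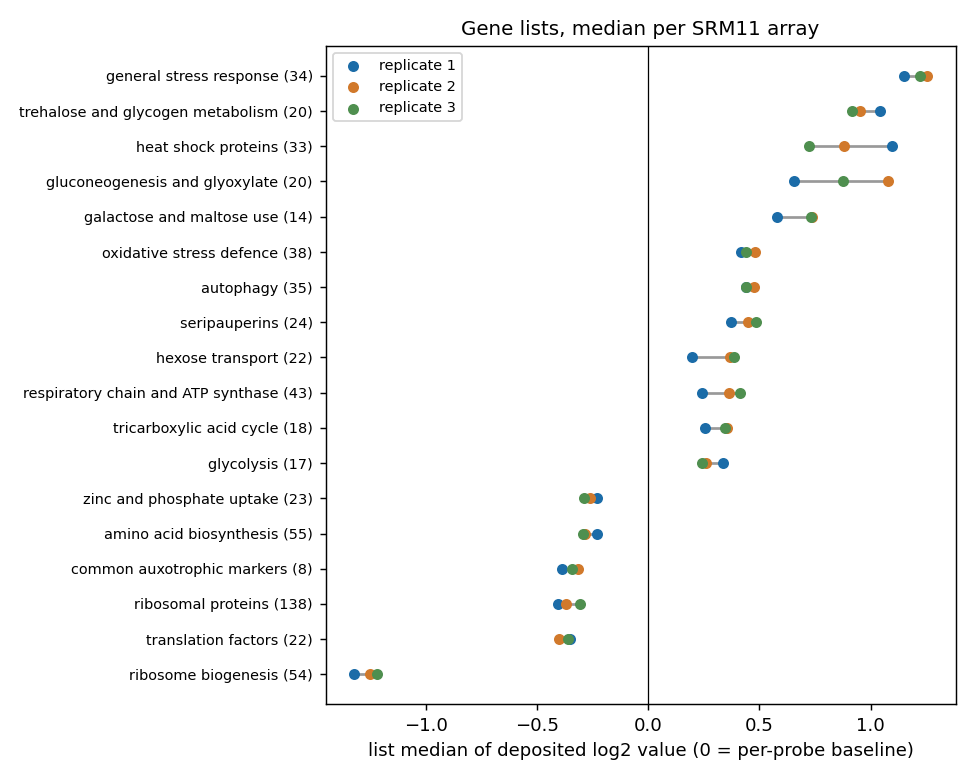
Median deposited log2 value (horizontal axis, 0 is the baseline of each probe) of the 18 gene lists that differed from other genes with camera at its preset correlation, with 1 coloured point per SRM11 array and list sizes in parentheses. The 3 arrays lie on the same side for each list, from a median of 1.20 over the 3 arrays for the general stress response to -1.26 for ribosome biogenesis.

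Of the 36 lists 12 lay higher and 6 lower than other genes with camera, and the remaining 18 were not called. None of the 36 was called with an estimated correlation, where the smallest adjusted p was 0.338 and 5 lists had an unadjusted p under 0.05. That test rests on 2 residual degrees of freedom and has little power, so its lack of calls decides nothing about a list. The calls at the preset, in turn, rest on the assumed correlation of 0.01. With fry, 32 lists had an adjusted p under 0.05. Among lists without a call, single members still moved. The G1 cyclin gene CLN2 fell by 1.15 ± 0.18 (SD, n = 3) on the log2 scale. Of 41 genes of nutrient signalling and lifespan 18 rose and 14 fell, with a median of 0.05. In that list RAS1 lay at -1.78 ± 0.10 and SIR2, a deacetylase gene, at -0.97 ± 0.04, while TPK2 rose by 1.11 ± 0.03 and GIS1 by 1.04 ± 0.01. The inositol synthesis gene INO1 rose by 1.63 ± 0.09, the vacuolar mannosidase gene AMS1 by 1.53 ± 0.01 and the metallothionein gene CUP1-1 by 1.45 ± 0.01. CUP1-1 is from the list of genes that vary in copy between laboratory strains, as is CUP1-2, which rose by 1.39 ± 0.02. Copy number was not tested. In the haploid genes, sulfur amino acid metabolism and meiosis, the median differed in sign from the mean, camera and fry, and in sterol and lipid synthesis, with a median of -0.04, fry alone pointed up. The whole comparison has a limit. The arrays in the baseline besides SRM11 are not described in the sources used here, so the strain and their batch cannot be told apart. All 20 spike-in control probes above background lay below the baseline in 3 of 3 arrays, so part of these distances may be technical. Apart from ribosome biogenesis, the lists called lower had medians within the range of the 7 E1A spike-in probes, -0.080 to -0.50.

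In SRM11 cultures, 5738 of 6256 genes (91.7%) were detected in all 3 arrays, 423 in none and 95 in 1 or 2 arrays. Among genes with a RefSeq locus 95.8% were detected, and 225 of the 500 probes without one. The highest signals belonged to genes of glycolysis and fermentation. FBA1, the aldolase gene, had a log2 signal of 18.33 ± 0.03 (SD, n = 3), GPM1 18.24 ± 0.05, TPI1 18.09 ± 0.06, ENO2 17.95 ± 0.04, ADH1 17.89 ± 0.05, CDC19 17.80 ± 0.06, PDC1 17.62 ± 0.07 and PGK1 17.62 ± 0.03. They were joined by the mitochondrial gene OLI1 at 18.09 ± 0.02, the peroxiredoxin gene AHP1 at 17.96 ± 0.09, the cell wall gene CCW12 at 17.71 ± 0.04 and the elongation factor gene TEF2 at 17.66 ± 0.09. Probes differ in how well they bind, so levels rank genes only roughly.

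By list, the glycolysis median of 17.22 was the highest, and its lowest members were PYK2 at 11.13 and PFK2 at 15.23. Heat shock protein genes had a median of 14.98, from HSP30 at 16.92 and HSP26 at 16.53 down to HSP33 at 9.63 and SSA3 at 8.82. Ribosomal protein genes had a median of 14.56, with RPS31 at 17.54 and RPS2 at 17.38 at the top and RPS30B at 10.61 and RPL7B at 7.47 at the bottom. At the other end, meiosis and sporulation genes had a median of 5.32, from DIT1 at 8.47 and NDT80 at 8.42 to MER1 at 2.31 and SPO77 at 2.12, which were not above background in any array. Of the 36 lists, 20 had a median above all but 2.5% of random lists drawn from all genes, and 5 had one below all but 2.5%.

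The median SD between arrays was 0.070 over detected genes, against 0.055 between the spots of one array, and Pearson's r of log2 signal across genes was 0.997 to 0.998, with genes not being independent replicates. Without replicate 1 the median SD was 0.041, and without replicate 2 or 3 it was 0.074 or 0.064. The value of an array is the median of 2 spots, so its SD and that between single spots are not like measures. The largest SDs fell into 2 kinds. ADH2, an alcohol dehydrogenase gene repressed by glucose, had an SD of 1.24 between arrays and 0.050 between spots. SFC1 had 0.82 and 0.076, FBP1, the fructose-1,6-bisphosphatase gene, 0.70 and 0.064, ADY2 0.68 and 0.085, and YGR035C 0.67 and 0.056. In TRM2, UTP23, YBL065W, SHB17 and ASF2 the spots of one array differed more than the arrays, with SDs between spots of 2.53, 1.95, 1.19, 1.03 and 1.06.

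Genes of gluconeogenesis, the glyoxylate cycle and non-fermentable carbon use varied most as a list. Their median SD of 0.24 lay above 100% of 10000 random lists matched on signal, and their median deviation from each gene's mean was -0.24, 0.19 and 0.03 in replicates 1, 2 and 3. Heat shock protein genes had a median SD of 0.17 (100th percentile) and deviations of 0.18, -0.06 and -0.12. Genes of galactose and maltose use and of hexose transport also exceeded the 99th percentile, with median SDs of 0.147 and 0.145 and deviations of -0.10 and -0.14 in replicate 1. Without replicate 1, heat shock protein genes fell to a percentile of 70.9, galactose and maltose use to 22.3 and hexose transport to 23.9, while gluconeogenesis stayed at 100, with a median SD of 0.11. Hexose transport was also under the 99th percentile without replicate 2 (97.4) and without replicate 3 (97.9). Galactose and maltose use was under it without scaling (82.0), with quantile normalization (98.1) and with the background-subtracted signal (98.3).

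**Figure D3:**
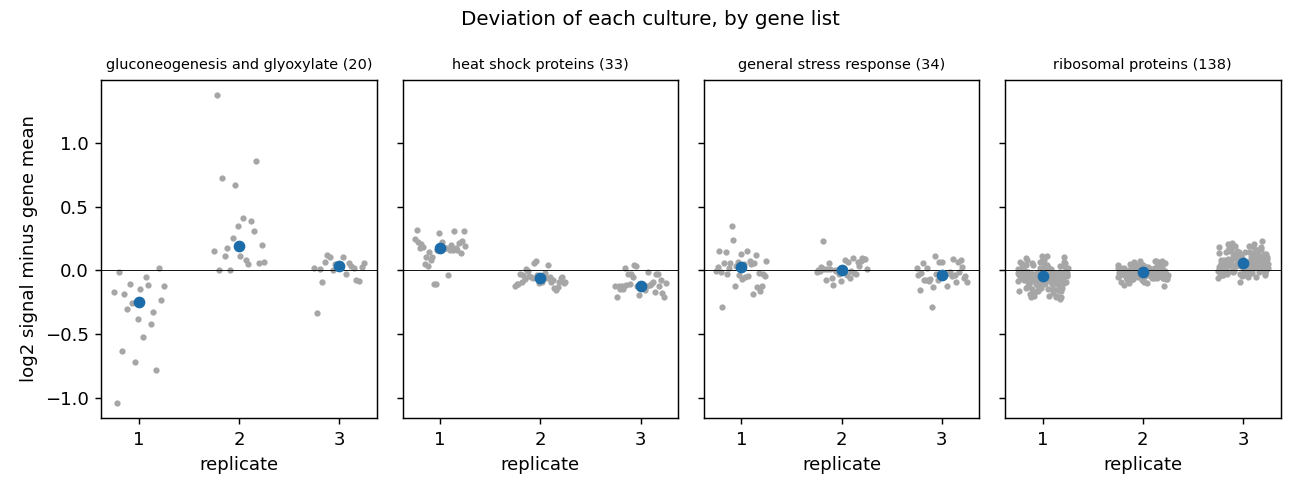
Deviation of log2 signal from the mean of each gene (vertical axis) in SRM11 replicates 1, 2 and 3 for 4 gene lists, with 1 grey point per detected gene and a blue point for the list median. Gluconeogenesis genes deviate by a median of -0.24 in replicate 1 and 0.19 in replicate 2, and heat shock protein genes by 0.18 in replicate 1.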

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

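All the tests of explanations in this part were chosen after the results had been seen.

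Spike-in control probes, which the comparison of genes does not use, lay away from the baseline. They read added control RNA and not transcripts of the strain. Their shift points to a technical difference between the SRM11 arrays and others in the baseline. Its size in gene probes is not known. All 20 spike-in control probes with signal above background lay below 0 in 3 of 3 arrays, while the negative control probe stayed within 0.039 of it. The 7 E1A spike-in probes lay between -0.080 and -0.50. Medians of ribosomal proteins (-0.36), translation factors (-0.38), amino acid biosynthesis (-0.27), zinc and phosphate uptake (-0.26) and auxotrophic markers (-0.35) lay within that range. By size alone, a technical shift was thus not excluded for these lists. Among random lists matched on signal, their medians lay at percentiles 0.0, 0.0, 0.0, 1.89 and 0.46, in that order. In 3 further families of control probes, names carry a number, and among probes above background the distance grew with it. It went down to -1.79 in the first family, -0.93 in the second and -1.40 in the third.

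The first pattern is the rise of general stress, heat shock and storage carbohydrate genes together with the fall of ribosome biogenesis genes. The control probes themselves did not rise: the highest spike-in probe lay at -0.080, while the lowest of the 3 list medians was 0.91. The 3 columns have the same mean, so lower values of some probes can go with higher values of others. The control probes therefore cannot decide whether a difference in hybridisation raised these genes. For the fall, a probe effect unrelated to gene function falls short. At least 2-fold below the baseline lay 44 of 54 ribosome biogenesis genes, and the most in any of 10000 random lists matched on signal was 13. A single culture does not account for either side, as the lowest stress list median in any array was 0.72 and the highest ribosome biogenesis median was -1.22. Another growth state at harvest than in the further arrays of the baseline may also account for both, with ribosomal protein genes at a median of -0.36; it cannot be told apart from the strain, because those arrays are not described in the sources used here, although the protocol names an OD600 of 1.0 for both strains.

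The second pattern is the 47 genes that were not above background in all 3 SRM11 arrays and lay at least 2-fold below the baseline, with a median of -1.34. Among them, chosen here after their values were seen, are the splicing factor gene PRP24 at -2.22 ± 0.13 (SD, n = 3) and KRE29 at -1.70 ± 0.11, both held to be essential for growth; neither was above background in any array, so background sets the size of these values. A candidate explanation is weaker signal of imperfectly matched probes on the SRM11 arrays, since a numbered control probe above background reached -1.79. Whether these gene probes match the strain imperfectly was not tested, as probe sequences were not used here. This explanation therefore cannot be told apart from lower expression. That control probe was above background in all 3 arrays, so the same explanation was not excluded for detected genes that fell. Loss of a DNA segment also stays open: 1 neighbouring pair, ARO3 and EHD3, was found among 29 of these genes with a RefSeq locus, and 33.7% of random draws of genes at background held as many, but 15 of the 47 genes were above background in 1 or 2 arrays, which argues against their loss.

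The third pattern is the difference between the arrays of the 3 cultures in genes of gluconeogenesis, the glyoxylate cycle and non-fermentable carbon use. Noise between spots is argued against by 19 of these 20 genes having their lowest signal in the same array, replicate 1, against at most 16 in 10000 lists of independent draws. Low signal is argued against by random lists matched on signal, in which at most 16 members were lowest in the same array. Scaling as the whole cause is argued against by the list's median SD, which was 0.24 as reported, 0.24 under quantile normalization and 0.19 without scaling, where the highest of 10000 matched random lists reached 0.159. How much scaling adds to the size of the difference is left open. Replicate 1 is not the whole of the pattern, since without it the percentile was still 100, with a median SD of 0.11. The labels give no group that separates the cultures, so no biological explanation was tested. With 1 array per culture, a difference between cultures cannot be told apart from one in RNA preparation, labelling or hybridisation.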

How the results depend on the processing

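The square-root-of-2 threshold, the variance trend, the RefSeq restriction, the median pixel signal, and the spread limited to genes with agreeing spots were chosen after seeing the data; the other alternatives were planned. The number of genes at least 2-fold above (270) and below (347) the baseline followed the fold threshold by construction: 720 and 822 at 1.5-fold, 76 and 85 at 3-fold, and 930 and 980 at the square root of 2. Under the other alternatives the counts stayed within 1.5 times, from 219 to 289 higher and from 278 to 358 lower. Of the 617 genes called, 579 to 595 were called alike without any one array, and none changed sign in the fits compared. Centring on the median left 607 of them. The lists called higher numbered 11 to 13 and those lower 6. Peroxisome genes were called after centring, in RefSeq probes and without replicate 1, and genes that vary in copy number among detected genes. Detected genes ranged from 4672 to 5970. The number of lists at a high level stayed at 20, while 5 of the 12 named gene levels moved by more than their SD over arrays, in 9 cases, all with the background-subtracted or median pixel signal. The median SD between cultures of 0.070 was 0.093 without scaling and 0.076 without the filter, and with 1 array left out it ranged from 0.041 without replicate 1 to 0.074 without replicate 2; the cause was not tested. The lists with a spread above the 99th percentile numbered 3 to 5 and were not always the same: without replicate 1 they were gluconeogenesis, ribosomal proteins and the respiratory chain, and sulfur amino acid metabolism entered in 4 settings and haploid genes without scaling. None of the genes or lists named in the comparison reversed its direction after a call. The raw mean spot signal was not in the data used here and was not run, and the mean of 2 spots equals their median. Counting each probe on its own changes nothing with 1 probe per gene. Splits of the samples into other groups could not be made with 1 group. No paired analysis was possible because the labels give 1 group. Signal over background limits what can be said of falls, since 423 genes were above it in no array.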

Other observations

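Transcripts encoded by the mitochondrial genome went both ways in SRM11. Of 19 probes, 6 lay at least 2-fold below the baseline, among them VAR1, a mitochondrial ribosomal protein gene, at -2.09 ± 0.31 (SD, n = 3), ATP8 at -1.09 ± 0.04 and the intron genes BI2, AI1, AI5_BETA and AI3. COX1, by contrast, rose by 0.78 ± 0.24 and COX2 by 0.39 ± 0.10. These genes were chosen after their values were seen, and 11 of the 19 probes were detected in all 3 arrays. BI2 and AI3 were not above background in any array and AI5_BETA was above it in 1, so background sets the size of their values. Medians of the 16 nuclear chromosomes lay between -0.03 and 0.10, so no whole chromosome stood apart.

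Among lists without a call, STE2, the receptor gene for alpha factor, fell by 0.93 ± 0.12 (SD, n = 3) on the log2 scale. Of 7 mating type a genes 3 rose and 3 fell, and of 7 mating type alpha genes 3 rose and 1 fell. MATALPHA1 and HMLALPHA1, which share sequence, lay at 0.77 ± 0.07 and 0.78 ± 0.10, with log2 signals of 8.62 and 8.63. HO, the mating-type switching endonuclease gene, lay at -0.97 ± 0.13. Proline use gene PUT1 rose by 1.42 ± 0.19 and the S-adenosylmethionine permease gene SAM3 fell by 1.31 ± 0.13 on the log2 scale.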
